A study of Mus musculus with 8 samples.

How the data were processed

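Total RNA from quadriceps muscle of 4 control and 4 hypoxia samples was hybridised to 8 Affymetrix whole-genome mouse arrays, 1 array per sample, per the labels. The deposited values are MAS5 signal intensities on a linear scale, 1 intensity per probe set and array. MAS5 is Affymetrix's algorithm that subtracts mismatch-probe background, summarises the probes of a set and scales each array by 1 factor. It is named in the submitters' processing notes, and its version, detection calls and further filters are not given in the sources used here. Every array's 2% trimmed mean signal was 499.8, so the authors' scaling to a common mean was kept, and no further normalization entered the main analysis. The median signal per array ran from 128 to 165. No 2 of the 8 arrays held identical values. All columns of the deposited table belonged to these 8 samples.

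Scaling each array to a common mean assumes that total signal is alike, and a change in the brightest transcripts then moves all others slightly, which is why quantile normalization and median centring were run as alternatives. MAS5 values of dim probe sets are noisy, and bright ones can saturate. Because the probes lie near the 3' end and labelling starts there, broken RNA lowers signals read farther from the 3' end, and the control probe sets for the 3' and 5' ends of Gapdh and beta-actin were therefore compared on each array. The number of arrays, and not a read depth, limits the precision.

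Groups and replicate numbers came from the sample titles. Of 45101 probe sets, 64 control probe sets and then the 40% with the lowest mean log2 value were left out, which left 27022 and put the filter at a signal of about 90.2. A table of the platform's annotation listed 35890 probe sets, of which 34958 had 1 gene symbol and 932 several, and 9211 were unlisted and stay unnamed. The symbols were matched through gene identifiers to mouse genes of the assembly GRCm38.p6 for 99.4% of the probe sets with 1 symbol, and no coordinates were taken from it. Of the probe sets past the filter 22840 had 1 symbol, and each of 13257 genes was represented by its probe set with the highest mean. Among 2298 called genes with other probe sets, 717 had at least 1 whose change had the opposite sign, and named genes of this kind are said to be uncertain where they passed. Where such a probe set is dim, near the filter, it says little against the brightest one.

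Signals were transformed as log2(signal + 16), which understates the fold change of dim genes. Hypoxia was compared with control using limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no block), with Benjamini-Hochberg adjustment over the 13257 genes and a threshold of 0.05. The 30 gene lists described in the report, with 706 members of which 609 were tested, were compared with all other genes by limma's camera with a preset correlation of 0.01 and adjustment over the 30 lists. Of the members that were not tested, 25 lay only on probe sets with several genes, 43 had no named probe set and 29 were below the filter. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera takes its degrees of freedom from the arrays, and with a preset one from the number of genes. The estimated form therefore has less power to detect a shift, whatever the correlation is. Fry tests whether a list's genes moved on balance in 1 direction and does not compare the list with other genes.

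Genes named in the text are the 12 with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap, leaving out provisional symbols, up to 4 members of each list with the smallest p, and 5 sex-linked genes. The tests, lists, naming rule and alternatives were fixed before the data were examined. Members were also named after their values were seen where 5 or fewer of a list moved in 1 direction, or where the text says that they were singled out.

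The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a 60% filter, all probe sets as units, the mean of a gene's probe sets, eBayes without the trend or with robust estimation, array weights, the replicate number as a block, and leaving out each array in turn. The procedure was tested on simulated data with 50 changed genes per size among 13257. It recovered 2% at a log2 change of 0.5, 52% at 1, 94% at 2 and 98% at 4, and called 3 unchanged genes. A simulated list shifted by 0.5 was called, and 0 of 29 unshifted lists were. The simulated genes were drawn independently of each other, so this does not show how the list test treats genes that vary together. Few genes were changed in the simulation, so its recovery shares need not hold where many genes change. A further 7 lists, written after the main results were known, cover neutrophil genes, acute-phase genes, fibroblast genes that are not in the matrix list, p53 targets, ATF4 targets, mitochondrial ribosomal proteins and translation initiation factors. None of their tested members stands in the 30 lists or among the named genes of the rule. Bootstrap intervals of list medians resample the genes of a list and not the samples. They treat genes as independent and do not cover the spread between samples.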

Results

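Gene expression was measured in the quadriceps muscle of adult male mice of the C57Bl/10 strain with Affymetrix whole-genome mouse arrays, on which sets of short oligonucleotide probes read the 3' part of transcripts. The 8 arrays formed 2 groups of 4. Control muscle came from mice kept in room air for 2 weeks. Hypoxia muscle came from mice in a closed chamber in which oxygen fell from 21% to 8% during the first week and stayed at 8% for 7 further days. The 1 comparison asked which transcripts of this locomotor muscle differed after sustained whole-body hypoxia. Only the hypoxia mice are described as kept in a closed chamber, so effects of the chamber and of low oxygen cannot be told apart. Each array held 45101 probe sets, and the number of arrays, 4 per group, limited the precision of every value. Nothing in the labels said that the RNA samples of a group came from separate animals beyond naming each quadriceps, so p-values measured only the spread between these samples. Changes are log2 differences of hypoxia minus control, computed on the signal plus 16, with standard errors (SE) from the limma fit. Signals are means ± SD over the 4 arrays of a group.

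After hypoxia many genes of glycolysis, glycogen breakdown, mitochondrial respiration, fast contraction and extracellular matrix had lower transcript levels in the quadriceps, and many genes of protein breakdown had higher ones. Tested as whole lists, these groups passed with a preset correlation between genes, but none passed with an estimated correlation, where the smallest adjusted p was 0.13. Of the tested glycolysis and glycogen genes, 19 of 24 fell, with a list median of -1.51 on the log2 scale. Of the matrix genes, 20 of 25 fell (median -1.51), and of the fast fibre genes 15 of 18 fell (median -0.64, or -0.29 with 11 lower after quantile normalization). Of the proteasome genes, 29 of 32 rose (median 0.91). In the list of atrophy genes and targets of glucocorticoids or FoxO factors, which is not confined to protein breakdown, 15 of 25 rose (median 0.96). Lcn2, which encodes an iron-binding secreted protein of inflammation, rose 59.8-fold, and Myoz3, which encodes a Z-disc protein of fast fibres, fell 59.1-fold.

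Of 13257 genes tested with limma, 4448 (33.6%) passed an adjusted p of 0.05, of which 1959 rose and 2489 fell. At least 2-fold changes were found for 784 of the genes that rose and 1181 of those that fell. In 4432 genes (33.4%) the 4 hypoxia values did not overlap the 4 control values, where chance gives 2.86%. Arrays correlated more closely within a group than between groups across genes, which are not independent replicates: r lay between 0.951 and 0.961 within control, between 0.936 and 0.960 within hypoxia, and between 0.857 and 0.891 across the groups. The first principal component, with 57.7% of the variance, separated the groups. The split between rises and falls depended on the scaling: 44.0% of called genes were higher with the deposited scaling, 50.2% (2263 higher, 2246 lower) after quantile normalization and 55.5% (2431 higher, 1952 lower) after median centring. The median change of all tested genes was -0.04 with the deposited scaling and 0.09 after median centring, so small changes have no firm direction, least of all falls smaller than the difference between these medians.

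RNA quality measures differed between the groups. The ratio of 3' to 5' signal of the Gapdh control probe sets, which rises when transcripts are broken or incompletely copied, was 3.44 in hypoxia 1, against 0.801 to 0.874 in the other 3 hypoxia arrays and 0.776 to 0.807 in the 4 control arrays. The same ratio for beta-actin was 2.53 in hypoxia 1, 1.40 to 1.59 in the other hypoxia arrays and 1.09 to 1.25 in control, so that it was higher in every hypoxia array than in any control array. Spike-in transcripts, which are added to samples in fixed amounts, differed along the groups as well in 3 of the 4 hypoxia arrays. They report on hybridization and scaling and not on the integrity of the sample's RNA. In hypoxia 2 to 4 the scaled signals were 756 to 1050.3 for BioB, 2306 to 2467 for BioC and 24771 to 28087 for CreX, below those of every control array (1166 to 1511, 3353 to 4406 and 33909 to 39355). Without hypoxia 1, 1937 genes were higher and 2466 lower, of which 1760 and 2257 were also called with all 8 arrays.

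**Figure D1:**
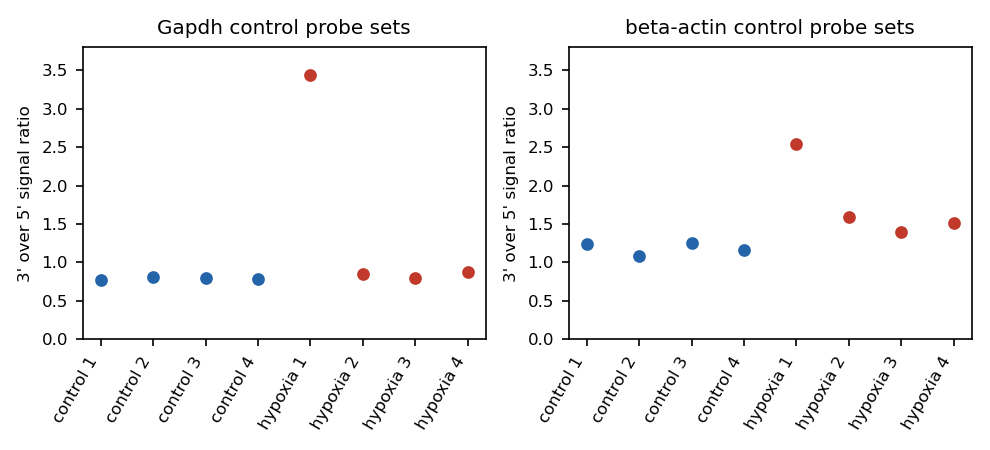
Ratio of 3' to 5' signal (linear axis from 0, no unit) of the Gapdh and beta-actin control probe sets on each of the 8 arrays, with control arrays in blue and hypoxia arrays in red. Hypoxia 1 stands at 3.44 for Gapdh and 2.53 for beta-actin, and the other 7 arrays lie below 1.6 in both panels.

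The 12 largest rises among called genes with no overlap between the groups began with Lcn2. It rose from a signal of 45.7 ± 48.1 to 3285 ± 1639.5 (n = 4 per group, log2 change 5.90 ± 0.42, adjusted p = 7.18e-07). Ankrd1, a titin-associated ankyrin-repeat protein induced by muscle stress, rose 51.5-fold from 309.9 ± 57.8 to 17199 ± 5413. Sln encodes sarcolipin, a small inhibitor of the calcium pump of the sarcoplasmic reticulum, and rose 49.2-fold from 245 ± 116 to 13270 ± 7458 on its brightest probe set, while its other probe set changed by -0.42 and did not pass the test, so the change of Sln is uncertain. Rrm2, the small subunit of ribonucleotide reductase, rose 37.2-fold, and Chil3, a chitinase-like protein secreted by macrophages, rose 30.9-fold. Igfbp3, which binds insulin-like growth factors, rose 21.5-fold from 328 ± 23.7 to 7409.5 ± 746 (adjusted p = 2.32e-09). Ampd3, an AMP deaminase, rose 19.7-fold, and Perp, a tetraspan membrane protein known as a p53 target, rose 17.8-fold. The remaining rises were S100a9, a subunit of calprotectin (15.3-fold), Cd68, a lysosomal protein of macrophages (15.2-fold), Plekha5 (14.3-fold) and Mustn1, a nuclear protein of the musculoskeletal system (13.5-fold). Control signals of Lcn2, Rrm2, Chil3, S100a9 and Plekha5 averaged below 90.2, the signal at the filter on dim probe sets, so their folds depend on the constant added before the logarithm. Rrm2 and Plekha5 were read by probe sets that can also bind related transcripts, and other probe sets gave smaller rises of Rrm2 (3.09 and 4.21) and Igfbp3. A probe set shared by Chil3 and Chil4 gave a smaller rise too (2.63), so the size of the Chil3 rise is uncertain.

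The 12 largest falls began with Myoz3. It fell from 2056 ± 406 to 18.7 ± 3.59 (n = 4 per group, log2 change -5.88 ± 0.20, adjusted p = 4.13e-09). Plcd4, a phospholipase C, fell 49.8-fold, Atp1b2, a subunit of the sodium-potassium pump, fell 32.5-fold, and Lrrc38, an auxiliary subunit of potassium channels, fell by 4.86 on the log2 scale. Fmod, the matrix proteoglycan fibromodulin, fell 25.4-fold from 6829 ± 1129.9 to 288 ± 152, and Nrep fell 24.7-fold. Grb14, an adaptor that binds the insulin receptor, fell 23.5-fold, and Mss51, a muscle protein located at mitochondria, fell 22.3-fold from 11682 ± 3364 to 492 ± 43.9. Smox, the spermine oxidase of polyamine breakdown, fell 21.2-fold from 12660 ± 3788 to 581 ± 183. Pi16, Fam131a and Ky, a muscle protein needed for normal growth of postural muscle, fell 21.9-fold, 17.2-fold and 16.3-fold. Hypoxia signals of Myoz3, Plcd4, Atp1b2, Lrrc38, Grb14, Pi16 and Fam131a averaged below 90.2, and Fmod and Nrep were read by probe sets that can bind related transcripts. The folds of this paragraph are those of the brightest probe set, and others gave smaller falls: -1.53 for Atp1b2, -2.29 to -3.67 on 5 for Fmod, and -1.61 for Smox, so the sizes of these 3 falls are uncertain.

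**Figure D2:**
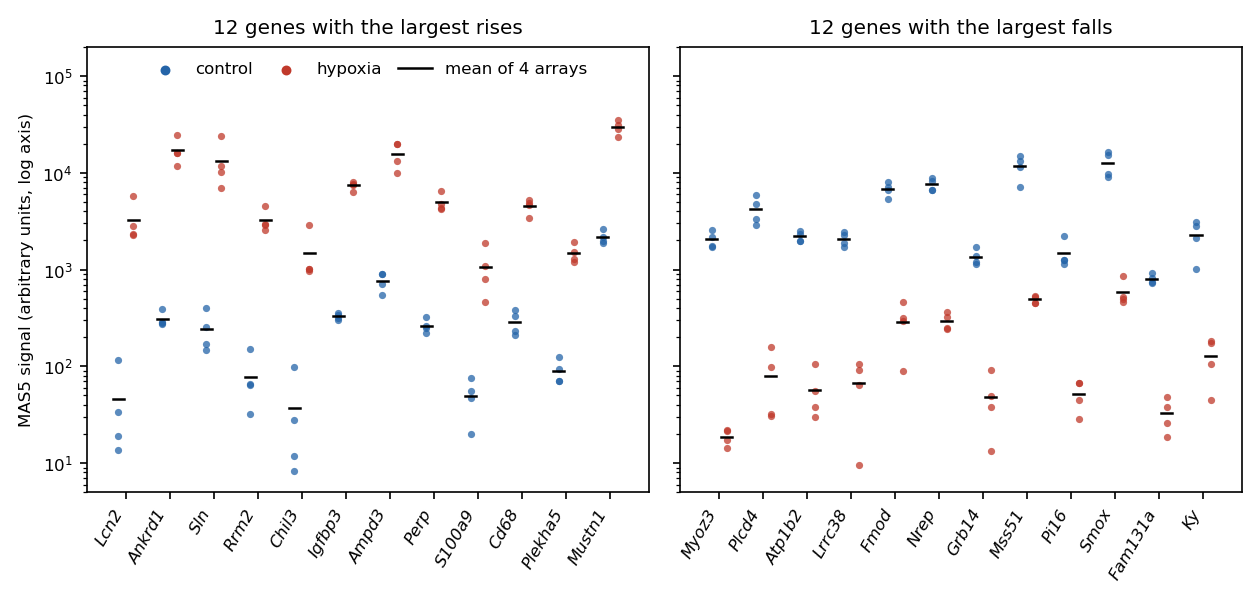
MAS5 signal in arbitrary units on a logarithmic axis for the 12 genes with the largest rises and the 12 with the largest falls, with 1 point per array, control in blue, hypoxia in red and a bar at the mean of 4 arrays. Every hypoxia point of Lcn2 lies above every control point, around means of 45.7 and 3285, and the order is turned for Myoz3, with means of 2056 and 18.7.

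Genes of glycolysis and glycogen metabolism fell from phosphorylase kinase to lactate dehydrogenase. Of 24 tested genes 19 fell and 1, Gbe1, the glycogen branching enzyme, rose by 1.76 (1 higher and 19 lower when adjusted over the list alone; adjusted p = 1.86e-10 by camera, and adjusted p = 0.13 with an estimated correlation). Phkg1 and Phka1, the catalytic and a regulatory subunit of muscle phosphorylase kinase, fell 12.8-fold and 12.5-fold, the latter from 15194 ± 1228 to 1246 ± 426 (n = 4 per group). Pgm1, which links glycogen to glycolysis, fell 8.62-fold from 19353 ± 1709.9 to 2272 ± 527 (adjusted p = 9.08e-08). Gpd1, the cytosolic glycerol phosphate dehydrogenase, fell 11.3-fold. Other probe sets gave less for Gpd1 (-2.58 and -0.99) and Pgm1 (-0.62, not passing), so the sizes of these falls are uncertain. Pfkm and Ldha, singled out after their values were seen as the muscle phosphofructokinase and a lactate dehydrogenase subunit, changed by -2.42 ± 0.17 and -1.97 ± 0.12 (SE), and both passed the test. RNA integrity also differed between the groups, as given above, and without hypoxia 1 the count was again 19 lower and 1 higher.

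Many transcripts of mitochondrial respiration were lower as well. Of the complex I subunits, 24 of 34 fell and none rose (0 higher and 27 lower when adjusted over the list alone; median -0.62; adjusted p = 3.56e-08 by camera, and adjusted p = 0.222 with an estimated correlation). Ndufb2 fell 2.61-fold from 18408 ± 1226 to 7048 ± 533, Ndufs1 fell 2.40-fold and Ndufa9 fell 2.05-fold. Ndufs8 fell 3.18-fold, and 1 of its 5 other probe sets changed by 0.05 in the other direction, so its change is uncertain. Of complexes II to IV, 16 of 30 genes fell and none rose (0 higher and 19 lower when adjusted over the list alone; median -0.53; adjusted p = 1.36e-05 by camera, and adjusted p = 0.222 with an estimated correlation). Cox7a1, the muscle form of a cytochrome oxidase subunit, fell 4.98-fold from 16876 ± 1544 to 3715 ± 2044, Cyc1 fell 2.85-fold, Uqcr11 fell 2.23-fold and Uqcrc1 fell 2.17-fold. Of the ATP synthase genes, 11 of 16 fell and none rose (0 higher and 13 lower when adjusted over the list alone; median -0.53; adjusted p = 2.81e-05 by camera, and adjusted p = 0.222 with an estimated correlation). Atp5e fell 2.02-fold from 18324 ± 69.1 to 9175 ± 1683, Atp5g1 fell 1.75-fold and Atp5o fell 1.67-fold. Atp5c1, at -0.77, has a second probe set at 0.19 without passing and is uncertain. That second probe set was dim, with a mean log2 value of 7.01 against 14.98, and says little. Without hypoxia 1 these 3 lists held 29, 21 and 14 genes that fell, but after median centring 17, 10 and 7, and the median of complexes II to IV was -0.33 after quantile normalization.

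Genes of fuel entry into the mitochondrion were affected too. In the tricarboxylic acid cycle and pyruvate dehydrogenase list, 15 of 22 genes fell and none rose (1 higher and 16 lower when adjusted over the list alone; median -0.71; adjusted p = 1.36e-05 by camera, and adjusted p = 0.153 with an estimated correlation). Suclg1, a subunit of succinyl-CoA ligase, fell 2.77-fold from 13600 ± 505 to 4956 ± 845. Pdp1, the phosphatase that activates pyruvate dehydrogenase, fell 2.59-fold, Dlat, the E2 component of the complex, fell 2.15-fold, and Idh3a fell 1.92-fold. Fatty acid genes were mixed, with 14 of 26 lower and 4 higher (5 higher and 15 lower when adjusted over the list alone; median -0.71; adjusted p = 0.0285 by camera, and adjusted p = 0.356 with an estimated correlation). The call was lost with a 60% filter (adjusted p = 0.0548). Acaa2, Decr1 and Acads, enzymes of beta-oxidation, fell 4.16-fold, 3.10-fold and 2.58-fold. The 4 that rose were Eci2 (2.59-fold), the thioesterase Acot2 (0.93), the fatty acid transporter Cd36 (0.61) and Acadl (0.50). The 20 mitochondrial regulators did not pass as a list (adjusted p = 0.225 by camera, and adjusted p = 0.319 with an estimated correlation), with 5 lower and 2 higher (2 higher and 5 lower when adjusted over the list alone; median -0.19). Ppargc1b, a coactivator of mitochondrial genes, fell 10.3-fold, the deacetylase Sirt3 fell 3.89-fold and Rxrg fell 3.51-fold. Prkaa2 changed by -1.01, Gabpa by 0.62 and Mfn2 by 0.76, and all 3 passed. Esrra changed by -1.22 but is uncertain, with a second probe set at 0.20, and Ppargc1a, singled out after its value was seen, changed by 0.35 ± 0.18 (SE) and did not pass.

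Many contractile and calcium-handling genes of fast fibres fell. Of 18 fast fibre genes, 15 fell and none rose (0 higher and 16 lower when adjusted over the list alone; adjusted p = 3.15e-08 by camera, and adjusted p = 0.18 with an estimated correlation). Pvalb, the calcium buffer parvalbumin, fell 4.87-fold from 53013 ± 6219 to 10822 ± 501, and Casq1, the fast calsequestrin, fell 8.55-fold from 33810 ± 3218 to 4061 ± 1214 (n = 4 per group, adjusted p = 2.33e-07). Sypl2, a triad membrane protein, fell 11.6-fold, and Myoz1, a Z-disc protein, fell 2.60-fold. Among the fast myosin heavy chains, singled out after their values were seen, Myh2 changed by -1.83 ± 0.36 (SE), Myh4 by -0.47 ± 0.14 and Myh1 by -0.40 ± 0.19, of which Myh2 and Myh4 passed. Without hypoxia 1, 17 of the 18 fast fibre genes fell, but 11 did after quantile normalization (median -0.29) and 9 after median centring (median -0.51). In the calcium release list 10 of 15 genes fell and 2 rose (2 higher and 11 lower when adjusted over the list alone; median -1.02; adjusted p = 0.00131 by camera, and adjusted p = 0.191 with an estimated correlation). Stac3, Cacnb1 and Jph2, which couple the surface calcium channel to the release channel, fell 8.39-fold, 7.39-fold and 4.60-fold, and the 2 rises were Sln, given above, and Cacng1 (0.91). Other probe sets of Cacnb1 (-1.97, and -0.01 without passing) and Jph2 (-0.74) gave less, so the change of Cacnb1 is uncertain. Slow fibre genes did not shift (adjusted p = 0.622 by camera, and adjusted p = 0.873 with an estimated correlation), with 2 of 15 higher and 2 lower (2 higher and 2 lower when adjusted over the list alone), and their median of -0.14 (0.03 after quantile normalization) and mean of 0.15 differed in sign. The members that rose, Ankrd2 (7.40-fold) and Csrp3 (3.96-fold), encode stretch-responsive Z-disc and titin-associated proteins and not contractile filaments. Mb, the oxygen-binding myoglobin, fell 2.23-fold from 50109 ± 5415 to 22715 ± 4483, and the slow myosin light chain Myl3 fell 3.64-fold. Other probe sets of Myl3 gave less, at -1.47 and, without passing, -1.06.

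Genes of protein breakdown rose. Of 32 proteasome genes 29 rose and none fell (31 higher and 0 lower when adjusted over the list alone; adjusted p = 3.62e-15 by camera, and adjusted p = 0.153 with an estimated correlation). Psma7 rose 2.80-fold from 5121 ± 270.0 to 14433 ± 1739 (n = 4 per group), Psmd2 rose 2.54-fold, Psma4 rose 2.39-fold and Psmd8 rose 2.16-fold from 10668 ± 748 to 23069 ± 1658. In the list of atrophy genes and targets of glucocorticoids or FoxO factors, 15 of 25 rose and 2 fell (15 higher and 3 lower when adjusted over the list alone; adjusted p = 2.42e-07 by camera, and adjusted p = 0.18 with an estimated correlation). Sesn1, a stress-induced inhibitor of mTORC1 signalling, rose by 3.59 on the log2 scale, with its 3 other probe sets at 3.55, 4.24 and 1.08, and Cdkn1a, the cell cycle inhibitor p21, rose 7.04-fold from 1328 ± 417 to 9172 ± 1314. Eif4ebp1, which blocks cap-dependent translation, rose 6.64-fold, and the transcription factor Cebpd rose 3.92-fold. The 2 falls were Foxo4 (-1.05) and the glucocorticoid receptor Nr3c1 (-0.61). Among members singled out after their values were seen, the metallothioneins Mt1 and Mt2 changed by 3.57 ± 0.41 and 3.50 ± 0.32 (SE), the ubiquitin ligase Trim63 by 1.03 ± 0.13 and the ligase Fbxo32 by 0.26 ± 0.16, which alone of these 4 did not pass. Autophagy and lysosome genes followed in part, with 7 of 20 higher and 1, the kinase Ulk1 (-0.62), lower (8 higher and 1 lower when adjusted over the list alone; median 0.24; adjusted p = 0.00397 by camera, and adjusted p = 0.18 with an estimated correlation). The lysosomal protease Ctsl rose 4.89-fold from 5978 ± 710.1 to 29397 ± 4478, Gabarapl1 rose 3.16-fold and Nbr1 rose 2.83-fold. Another probe set of Nbr1 stood at 0.67 without passing. Map1lc3b rose 2.41-fold on its brightest probe set, but its other 2 stood at 0.24 without passing, as did another of Ctsl at 0.44, so the change of Map1lc3b is uncertain. Among cytosolic ribosomal proteins 13 of 31 were higher and none lower (14 higher and 0 lower when adjusted over the list alone; median 0.30; adjusted p = 0.000272 by camera, and adjusted p = 0.41 with an estimated correlation), and many of the listed members have no probe set of their own. After quantile normalization 21 were higher (median 0.51), and without hypoxia 1 the median was 0.19. Rps25 rose 5.55-fold, and Rpl19, Rps19 and Rpl37 rose 1.86-fold, 1.80-fold and 1.84-fold. Ribosomal protein genes have many processed copies, so their probe sets are uncertain.

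Growth signalling and polyamine genes moved in both directions without a shift of the list, with 5 of 14 higher and 4 lower (6 higher and 6 lower when adjusted over the list alone; median -0.23; adjusted p = 0.815 by camera, and adjusted p = 0.867 with an estimated correlation). Igfbp5, which binds insulin-like growth factors, fell 14.9-fold from 8397 ± 2110 to 539 ± 71.7, beside Smox, but another probe set of Igfbp5 stood at -0.57 without passing, so its change is uncertain. Sat1, which acetylates polyamines for export, rose 3.72-fold. Igf1 changed by -1.45, Irs1 by -0.91, Mtor by 1.33, Insr by 0.59 and Akt2 by 0.57, and all passed. Akt1 rose by 2.45 on its brightest probe set, but its other probe sets stood at -0.59 and -0.04 without passing, so it is uncertain.

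Targets of the hypoxia-inducible factors (HIF) outside the glycolysis list were mixed. Of 25 tested genes, 11 rose and 4 fell (12 higher and 4 lower when adjusted over the list alone, median 0.27), and the list did not pass (adjusted p = 0.0627 by camera, and adjusted p = 0.18 with an estimated correlation). Glycolytic enzymes were left out of the HIF list and counted in the glycolysis list, where 19 of 24 genes fell, so these counts do not cover all HIF targets. Egln3, a prolyl hydroxylase that marks HIF for degradation, rose 4.62-fold from 1173 ± 313 to 5388 ± 996 (n = 4 per group, adjusted p = 5.49e-06), and the histone demethylase Kdm3a rose 2.21-fold. Pdk1, an inhibitory kinase of pyruvate dehydrogenase, rose by 1.11 on its brightest probe set, but another of its probe sets fell by 0.78, so it is uncertain. The 4 that fell were the transferrin receptor Tfrc (4.22-fold), the collagen prolyl hydroxylases P4ha1 (-1.27) and P4ha2 (-0.70), and Fam162a (-0.73). Vegfa, the vascular growth factor, singled out after its value was seen, changed by -0.36 ± 0.18 (SE) and did not pass. Antioxidant genes rose in 8 and fell in 2 of 18 cases (8 higher and 2 lower when adjusted over the list alone; median 0.14), and the list did not pass (adjusted p = 0.119 by camera, and adjusted p = 0.222 with an estimated correlation). Txn1 (thioredoxin) and Gsr (glutathione reductase) rose 2.80-fold and 2.37-fold. Their other probe sets stood at 0.18 for Txn1 and 0.53 for Gsr without passing. Gsta4 fell 5.64-fold and Sod3 changed by -1.79. Gclc rose by 1.07, but its other probe set stood at -0.19, so it is uncertain.

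Chaperone, clock and immediate early genes did not shift as lists. For heat shock and the unfolded protein response, 8 of 25 rose and 3 fell (8 higher and 4 lower when adjusted over the list alone; median 0.01, below 0 after quantile normalization; adjusted p = 0.276 by camera, and adjusted p = 0.588 with an estimated correlation). Xbp1, Dnajb9 and Hspe1 rose 1.89-fold, 1.92-fold and 1.59-fold, and Dnajb1 (-1.36), Dnaja1 (-0.91) and Hspb6 (-0.80) fell. In the circadian clock list 5 of 16 rose and 1 fell (5 higher and 1 lower when adjusted over the list alone; median 0.27; adjusted p = 0.0639 by camera, and adjusted p = 0.191 with an estimated correlation). Cry2 rose 3.37-fold from 945 ± 55.4 to 3318 ± 903, Per2 and Ciart changed by 1.24 and 2.11, and Dbp, an output gene of the clock, fell 2.36-fold. Rora rose 2.13-fold but is uncertain, with 1 of its 6 other probe sets at -0.24 without passing and the rest above 0. Clock itself was 0.86 on its brightest probe set and -0.81 and -0.73 on 2 of the other 3, so it is uncertain. Among immediate early genes 4 of 21 rose and 3 fell (4 higher and 4 lower when adjusted over the list alone; adjusted p = 0.962 by camera, and adjusted p = 0.99 with an estimated correlation), and the list's median of -0.39 and mean of -0.25 differed in sign from the upward direction of the test, which turned downward after quantile normalization. Myc rose 7.56-fold and Ier3 rose 4.60-fold, Ccn2 and Maff changed by 0.70 and 1.08, and Nr4a1 (-2.23), Klf4 (-1.10) and Dusp1 (-1.04) fell. Without hypoxia 1, 2 immediate early genes rose and 1 fell, and Klf4 no longer passed.

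Extracellular matrix genes fell in most cases. Of 25 genes 20 fell and 1 rose (2 higher and 20 lower when adjusted over the list alone; adjusted p = 1.88e-10 by camera, and adjusted p = 0.171 with an estimated correlation). Col1a2, a chain of the main fibrillar collagen, fell 10.9-fold from 6437 ± 404 to 577 ± 52.1 (n = 4 per group, adjusted p = 5.69e-09), and Col3a1 fell 12.6-fold. The proteoglycan Lum fell 12.8-fold and Col6a1 fell 5.94-fold. Lox, which crosslinks collagen, rose by 1.44. Basement membrane collagens Col4a1 and Col4a2, singled out after their values were seen, changed by -0.28 ± 0.15 and 0.02 ± 0.15 (SE) and did not pass. Without hypoxia 1, 20 again fell and 1 rose.

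Markers of other cell types moved in part. Endothelial and vessel markers did not pass as a list (adjusted p = 0.0639 by camera, and adjusted p = 0.533 with an estimated correlation), with 9 of 24 lower and 2, Tal1 (1.44) and Pdgfrb (0.53), higher (2 higher and 10 lower when adjusted over the list alone; median -0.34). Without hypoxia 1, 8 were lower and none higher. Angpt1, Cldn5 and the smooth muscle actin Acta2 fell 3.46-fold, 2.13-fold and 1.98-fold. Aplnr fell by 2.77 on its brightest probe set, but its other probe set stood at 0.06, so it is uncertain. Pecam1 and Cdh5, pan-endothelial genes singled out after their values were seen, changed by 0.16 ± 0.36 and 0.10 ± 0.31 (SE) and did not pass. Macrophage and other immune markers split, with 9 of 24 lower and 3 higher (3 higher and 10 lower when adjusted over the list alone; median -0.47; adjusted p = 0.0639 by camera, and adjusted p = 0.621 with an estimated correlation). The 3 that rose were Cd68, S100a9 and S100a8 (9.50-fold from 271 ± 128 to 2508 ± 419.6), and H2-Aa, a class II antigen-presenting molecule, fell 14.7-fold from a mean of 4127 to 266. Adipocyte markers fell in 10 of 12 cases and none rose (0 higher and 10 lower when adjusted over the list alone; median -1.34; adjusted p = 0.00239 by camera, and adjusted p = 0.319 with an estimated correlation). Scd1 and Fasn, lipid synthesis enzymes that muscle also expresses, fell 10.2-fold, with another probe set at -1.29, and 3.61-fold, Cidec of the lipid droplet fell 5.42-fold, and the secreted Adipoq fell 4.05-fold from 7359 ± 5595 to 1614 ± 987, with overlap between the groups. Nerve and Schwann cell markers did not pass (adjusted p = 0.225 by camera, and adjusted p = 0.562 with an estimated correlation), with 3 of 8 lower (0 higher and 4 lower when adjusted over the list alone; median -0.47), namely Cnp (2.40-fold), Pmp22 (-0.51) and S100b (adjusted p = 0.0478), while Mbp changed by -0.59 without passing and has a probe set at 0.92. Of 7 erythroid and blood genes only Bpgm, which makes 2,3-bisphosphoglycerate and is also expressed outside blood, fell (6.39-fold; 0 higher and 1 lower when adjusted over the list alone; adjusted p = 0.622 by camera, and adjusted p = 0.716 with an estimated correlation), and the list's median of 0.14 and mean of -0.29 differed in sign. Car2, Slc4a1 and Hba-a2 changed by -0.37, 0.29 and 0.45 without passing.

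**Figure D3:**
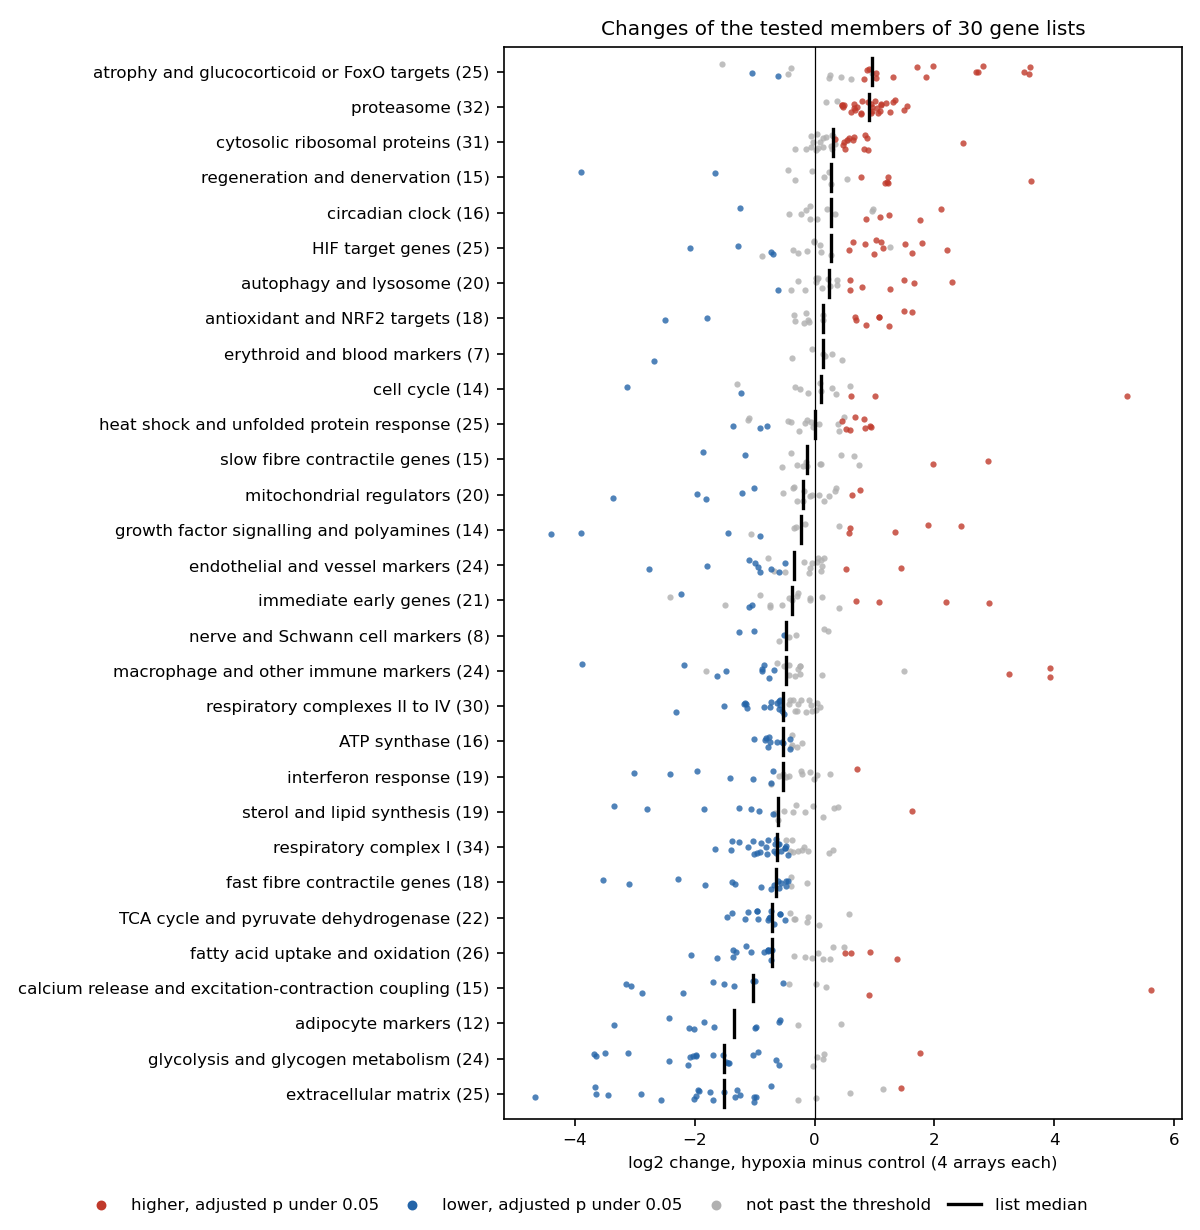
Log2 change of hypoxia minus control for each tested member of the 30 gene lists, with the number tested in brackets; red and blue points passed an adjusted p of 0.05 upward and downward, grey points did not, and black bars are list medians. Medians run from -1.51 for extracellular matrix to 0.96 for atrophy and glucocorticoid or FoxO targets.

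Regeneration and denervation genes shifted up by a small margin, with 6 of 15 higher and 2 lower (6 higher and 2 lower when adjusted over the list alone; median 0.28; adjusted p = 0.043 by camera, and adjusted p = 0.18 with an estimated correlation), and the call was also lost after median centring (adjusted p = 0.058). Gadd45a, a stress gene induced by denervation, rose 12.2-fold from 489.6 ± 123 to 6046 ± 988, Myf6, a myogenic factor of adult fibres, rose 2.33-fold, and Musk, the kinase of the neuromuscular junction, rose 2.35-fold. Actc1, the cardiac actin of developing muscle, fell 15.0-fold from 4303 ± 2188 to 281 ± 154, and Myod1 changed by -1.66. Interferon response genes fell in 7 and rose in 1, Tap1 (0.71), of 19 cases (1 higher and 7 lower when adjusted over the list alone; median -0.53; adjusted p = 0.0263 by camera, and adjusted p = 0.32 with an estimated correlation), and the call was lost with a 60% filter (adjusted p = 0.117). Ifi27l2a, Ifit3 and Oasl2 fell 8.12-fold, 5.31-fold and 2.04-fold, and Psmb8, an immunoproteasome subunit, fell 3.88-fold. Sterol and lipid synthesis genes fell in 7 and rose in 1 of 19 cases (1 higher and 7 lower when adjusted over the list alone; median -0.61; adjusted p = 0.0414 by camera, and adjusted p = 0.18 with an estimated correlation), and the call was also lost without hypoxia 1 (adjusted p = 0.0634). Idi1 fell 2.41-fold beside Scd1 and Fasn, and Fdft1, squalene synthase, rose 3.08-fold. Cell cycle genes did not shift (adjusted p = 0.589 by camera, and adjusted p = 0.643 with an estimated correlation), with a median of 0.10. Of 14 genes 3 were higher, namely Rrm2, Bub1b (1.01) and Pcna (1.53-fold), and 2 lower, namely Aurka (8.82-fold) and Rrm1 (2.34-fold). Adjusted over the list alone, 4 were higher and 2 lower. The hypoxia signal of Aurka averaged 67.4, below 90.2, so its fold depends on the constant added before the logarithm.

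Of the 30 lists, 5 passed upward and 12 downward with camera's preset correlation of 0.01, and none with a correlation estimated per list. Other divisions of the 8 arrays into 4 and 4 gave up to 15 lists in 1 direction at the preset correlation. Some of these divisions mix the groups unequally and keep part of the real difference. Their counts therefore cannot show whether chance gives as many lists. The number of lists that passed is not in itself taken as evidence of coordinated shifts. That none passed with an estimated correlation is no evidence against shifts either, because that form has less power. Sterol and lipid synthesis had an estimated correlation of -0.023, below the preset one, and its adjusted p by camera still went from 0.0414 to 0.18. As a check of the labels, which describe male mice, Eif2s3y on the Y chromosome had signals of 2534 to 3097 in control and 5665 to 10043 in hypoxia, Uty 323 to 501 and Kdm5d 257 to 417 over the 8 arrays, and Xist, expressed from the inactive X chromosome, 90.4 to 168. Ddx3y was not analysed here.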

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

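The patterns weighed here were picked after the gene-level results were seen, and the test that sets endothelial against matrix genes was chosen only after its values were known. The counts of single genes were set against other divisions of the 8 arrays into 4 and 4. Of the 35 divisions only 1, the real one, gave 1959 genes higher, and only 1 gave 2489 lower, with 0 genes as the highest count of any other. The share of 1 in 35 is the smallest that 2 groups of 4 arrays can give, so chance is unlikely for these counts but not excluded. The counts of 0 add nothing, because a mixed division puts a group difference into the spread within its groups. Any difference that lies along the groups, RNA integrity included, would give the same share. For the lists the divisions cannot decide whether chance gives as many. In 1 direction or the other, 21 of the 35 divisions gave at least 5 lists, the number that passed upward. At least 12 lists, the number that passed downward, were given by 5 divisions, with 15 as the highest count of another division. Divisions that mix the groups unequally keep part of the real difference, so these counts are no reference free of it.

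The glycolysis and fast fibre lists, which fell, hold very bright probe sets. Among 10000 lists matched on mean expression none had a median as low as glycolysis (percentile 0), and 0.35% had one as low as fast fibre genes. This argues against compression of bright signals as the whole cause of the glycolysis fall. The matched lists drew genes independently, so the percentiles can be too extreme for genes that vary together. The estimated correlation was 0.0808 for glycolysis and 0.382 for fast fibre genes, for which the percentile decides less. Quantile normalization, which rescales by intensity, left glycolysis at a median of -1.45 but moved the fast fibre list from -0.64 to -0.29 with 11 genes lower, so an intensity-related part of the fast fibre fall stays open. Without hypoxia 1, the array with the high Gapdh ratio, the medians were -1.47 and -0.72, which argues against broken RNA on that array as the cause. The beta-actin ratio was also higher in the other 3 hypoxia arrays than in control, so a part played by RNA integrity or labelling stays open. The spike-in signals of these 3 were lower than in any control array, so a part played by scaling stays open too. Both differences lie along the groups. A response of the muscle to hypoxia, the difference the design names, is untested beyond the comparison itself.

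The fall of the extracellular matrix list stood at percentile 0 of matched lists, which again drew genes independently, and its median was -1.37 without hypoxia 1. An equal loss of interstitial tissue of every kind would lower vessel markers alike. The endothelial median lay 1.17 above the matrix median (95% bootstrap interval over genes 0.51 to 1.87), so vessel markers fell less than matrix genes in these samples. This is no test of that explanation, because the criterion was written after both medians were known and the interval does not cover the spread between samples. Loss of some kinds of tissue stays open, since the medians of adipocyte (-1.34), nerve (-0.47) and immune markers (-0.47) were also below 0. A candidate explanation is also a smaller share of fibroblasts. Of 19 fibroblast genes that are not in the matrix list 15 fell, such as Cd34 (-1.95 ± 0.27, SE) and Gsn (-1.17 ± 0.19). Dpt (-2.80 ± 0.20) fell too, but Dpt and Mfap5 encode matrix proteins, so these genes are not fully separate from the matrix fall. The median of the 19 was 0.34 above that of the matrix list, with an interval of -0.39 to 1.13 that includes 0. S100a4 rose by 1.94 against this, muscle and endothelium express several of these genes, and lower transcription in unchanged cell numbers would look alike.

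The joint rise of Lcn2, Chil3, S100a8 and S100a9 may come from neutrophils in the tissue or from an acute-phase response of resident cells. Of 12 other tested neutrophil genes 4 rose, Il1r2 (1.99 ± 0.37, SE), Clec4d, Ngp and Fpr2, and the median change was 0.37 with an interval of -0.06 to 1.11. That interval includes 0 and also the value of 1 set in advance, so neutrophils and their absence cannot be told apart. Over all 22 members with a probe set, dim ones included, the median was 0.17 (-0.09 to 0.54), which lies below 1 and would have spoken against neutrophils; the tested members were chosen for the reading after both values had been seen, because dim members near background exclude little. Of 19 other tested acute-phase genes 5 rose, among them Slc39a14 (2.57 ± 0.20), Ch25h and Osmr, and 1, Hp, fell by 1.79. Genes of secreted acute-phase proteins, Saa1 (0.79), Saa2 (0.59), Saa3 (0.58), Cp (0.06) and Lbp (0.07), did not pass. The median of 0.58 (0.27 to 0.80, over genes) lay above 0, so such a response stays possible, and both sources may hold together.

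Single arrays stood far from the other 3 of their group for 14 named genes and 2 control measures. This was 16 of 286 groups examined, where chance gives about 14.3, so single genes on this list need no explanation. On control 2, signals were 396 for Ankrd1 (others 272 to 290), 14937 for Ndufs1 (13548 to 13771) and 7839 for Psmd2 (6341 to 6554). On control 3 they were 2212 for Pi16 (1152 to 1256), 2441 for Pdp1 (3503 to 3659), 26 for Hba-a2 (107 to 132) and 11399 for Ifi27l2a (2082 to 2616). On control 4 they were 18221 for Atp5e (18347 to 18365), 2722 for Mbp (3299 to 3398), 863 for Cry2 (967 to 982) and 226 for Psmb8 (473 to 532). On hypoxia 3 they were 2913 for Chil3 (974.9 to 1018) and 4205 for Klf4 (2356 to 2504), and on hypoxia 4 the value was 15159 for Myf6 (21253 to 22546). The Gapdh ratio of 3.44 and a BioC spike-in signal of 4504 (others 2306 to 2467) both belonged to hypoxia 1, but that spike-in value lies near control (3353 to 4406), and it is the other 3 hypoxia arrays that lie below every control array.

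Probe sets that the comparison did not use also carried signal. Of 628 tested probe sets with several gene symbols, 148 were higher in hypoxia and 97 lower. Of 3554 tested probe sets with no gene named, 235 were higher and 288 lower.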

How the results depend on the processing

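All alternatives were planned. With all 27022 probe sets as units, 3368 were higher and 4422 lower, because more units were tested. The lists passing upward numbered 8 with fry and 0 with an estimated correlation, and downward 0 with an estimated correlation. Correlations estimated from few arrays are themselves imprecise, and most lay above the preset one. The estimated form also has less power whatever the correlation is, as given above. Under all other settings the counts of genes and lists stayed within 1.5 times the main ones. Leaving out 1 array gave 1634 to 1937 genes higher and 2107 to 2553 lower. With the replicate number as a block the counts were 1782 and 2300, and same-numbered samples did not deviate together (r of -0.07, 0.00, -0.04 and -0.02 across genes). Of 133 called named genes, 124 kept direction and call under every one of the 20 settings that tested them. Clock reversed to -0.049 with the mean of a gene's probe sets, where its probe sets disagree; S100b, Pmp22, Klf4, Pdk1, Atp5c1, Esrra, Akt1 and Gclc lost their call under at least 1 setting. List medians moved by over 1.5 times also for regeneration and denervation (0.18 without hypoxia 3, 0.55 with the mean of a gene's probe sets), autophagy and lysosome (0.37 after median centring), fatty acid uptake and oxidation (-0.45 with the mean of a gene's probe sets) and sterol and lipid synthesis (-0.36 without hypoxia 1), all in the same direction; 6 adipocyte markers fell without hypoxia 2. Signal near background limits genes below about 90.2.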

Other observations

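The extra lists of genes below were chosen after the main results were seen, and none of their tested members stands in the 30 lists of the comparison. Translation initiation factors rose: 22 of 32 tested genes were higher and none lower, with a median of 0.68 (95% bootstrap interval 0.40 to 0.83; adjusted p = 3.70e-08 by camera over these 7 lists, and adjusted p = 0.1 with an estimated correlation). Eif5b, which joins ribosomal subunits, changed by 1.71 ± 0.15 (SE), from a mean signal of 1399 to 4622. Eif6, a ribosome anti-association factor, changed by 1.67 ± 0.15, the helicase Eif4a1 by 1.25 ± 0.13 and Eif3c by 1.17 ± 0.17. Cap-binding Eif4e changed by -0.35 ± 0.13 without passing, beside the rise of its inhibitor Eif4ebp1. Without hypoxia 1 the median of the list was 0.62.

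Perp, Cdkn1a, Sesn1, Gadd45a and Bid (2.98) rose and are known p53 targets, which raised the hypothesis that p53 targets rose as a group. Other p53 targets shifted up at p = 0.0119 by camera (adjusted p = 0.0208 over the 7 lists, and adjusted p = 0.1 with an estimated correlation), with 8 of 19 higher and 4 lower. Trp53inp1 (2.88 ± 0.20, SE), Eda2r (2.48 ± 0.14), Rps27l (1.39 ± 0.19) and Mdm2 (1.05 ± 0.18) rose, and Polk (-1.26 ± 0.25), Phlda3, Ccng1 and Ei24 fell. Their median of 0.59 has an interval of -0.10 to 0.76 that includes 0, so a partial p53 response may be present; Cdkn1a, Sesn1 and Gadd45a are also known FoxO targets, and the 2 were not separated.

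The rises of Eif4ebp1 and Atf4 raised the hypothesis that ATF4 targets rose as a group. The other ATF4 targets did not shift (adjusted p = 0.227 by camera over the 7 lists, and adjusted p = 0.366 with an estimated correlation), with 7 of 24 higher and 2 lower and a median of 0.13 (-0.31 to 0.50, the upper end just below the 0.5 set in advance). The interval resamples genes and does not cover the spread between samples, so a rise of the whole group by 0.5 or more is not excluded. Slc7a5 (2.01 ± 0.64, SE), Psat1 (1.30 ± 0.32), Slc3a2 (1.14 ± 0.14) and Asns (1.07 ± 0.28) rose, and Phgdh (-1.95 ± 0.44) and Nupr1 fell.

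Mitochondrial ribosomal proteins were tested as a further part of the mitochondrion. They shifted down at p = 0.0329 by camera (adjusted p = 0.0461, and adjusted p = 0.21 with an estimated correlation), with 24 of 71 lower, 10 higher and a median of -0.27 (-0.41 to -0.13). Mrps11 (-1.58 ± 0.24, SE), Mrpl48 (-1.17 ± 0.14) and Mrps6 (-1.10 ± 0.14) fell, and Mrpl32 (1.40 ± 0.15) and Mrpl35 (0.99 ± 0.14) rose. This suggests at most a partial extension to mitochondrial translation.

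The extra lists of neutrophil, acute-phase and fibroblast genes had camera adjusted p of 0.0509, 0.00467 and 8.19e-07 over the 7 lists, and adjusted p = 0.185, 0.185 and 0.1 with an estimated correlation.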
